A study of Mus musculus with 9 samples.

How the data were processed

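Total RNA of 9 primary brown adipose cultures, 3 per group, was biotin-labelled and hybridised to Affymetrix mouse gene arrays by the standard protocol, per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale. The values were made with RMA, per the submitters' processing notes, which corrects background, normalizes quantiles between arrays and summarises probes. Its version is not given in the sources used here, and since RMA's own output is on the log2 scale, the linear scale was read from the range of the values. RMA makes the arrays' distributions alike, which removes a global shift of expression if there was one, and compresses changes of dim and of very bright probes. The median intensity per array ran from 70.7 to 72.8.

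Log2 of the deposited intensity was taken with no offset. Of 35432 probe sets, 21706 had 1 gene symbol in the platform annotation supplied with the table, 1605 had several and were not used, and 12121 were not listed and so are unnamed here. The annotation can be old; 21615 of the single-gene probe sets matched a RefSeq gene by Entrez identifier. That match was not used as a filter. The 21706 single-gene probe sets gave 19858 genes, 997 of them with more than 1 probe set, for which the brightest was taken. In no comparison did a called gene have another probe set called the other way. Genes whose probe set had a mean below the 40th percentile of all probe sets (5.59 on the log2 scale, intensity 48.2) were left out, 6523 in all, which left 13335. No probe-level detection calls were used, so levels near that value are close to background.

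Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 9 arrays in 3 groups, with 6 residual degrees of freedom, no covariate and Benjamini-Hochberg adjustment within each comparison at 0.05. All tests were two-sided. Subject numbers differ between the groups, so no block was fitted. The labels name no batch, scan date or culture day, so a batch that follows the groups cannot be told apart from treatment. No pair of arrays was identical; the pair that shared most held the same value in 2649 of 35432 probe sets, and such ties understate the spread of the genes they fall on. Of the genes tested 586 had identical values in all arrays of a group, and 6 of these were among the 138 called for HA155 against control. With 3 arrays against 3 an exact test of a single gene cannot go below p = 0.1, so only the model across genes is used. All 138 genes called for HA155 had groups that did not overlap, as did 16.8% of all genes tested in that comparison, where 10% of unchanged genes do by chance. Calling selects such genes, so their separation is no further support.

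The 27 gene lists, of adipocyte, metabolic, signalling, matrix, inflammatory, stress and other-cell genes, were fixed before the data were examined, as were the design, the rule for named genes and the alternative settings. Of their 748 entries 703 had a single-gene probe set. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 27 lists in each comparison. The correlation estimated from the arrays, fry and a rank version of camera were alternatives; fry asks whether a list's genes move one way and does not compare them with other genes. With the preset correlation 16, 13 and 17 lists passed for LPA against control, HA155 against control and LPA against HA155, and 9, 0 and 9 held with an estimated one. The versions of the test differ in more than the correlation. The brown adipocyte list had an estimated correlation of -0.0145, below the preset. Its camera adjusted p with HA155 still went from 0.000496 to 0.080. A call lost with the estimated version therefore does not by itself show that a list's genes move together. Named genes were the 10 largest rises and falls per comparison among called genes whose groups did not overlap, the 4 members of smallest p per list, and a fixed set of LPA receptor and adipocyte genes. Cd36, Adm, Meg3 and the value of Ccl9 with HA155, which the rule does not give, and the genes labelled or drawn in the plots were chosen after their values were seen; the adjusted p with HA155 was 0.0485 for both Cd36 and Ccl9.

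The procedure was tested on simulated data with 200 changed genes per run and each gene's residual spread, pooled over the 3 groups. For HA155 against control it recovered 20.9%, 76.1% and 98.2% of genes changed by 0.25, 0.5 and 1 on the log2 scale, with 6.08% of calls false, over 13335 genes. For LPA against control it recovered 21.5%, 74.9% and 99.1%, with 6.61% false. The real spread differed between the groups, with a median SD per gene of 0.054 with HA155, 0.074 in control and 0.107 with LPA. The recovered and false shares therefore describe groups of equal spread, which these are not. Lists of 25 genes shifted by 0.3 were found in 20 of 20 runs, with 0 of 540 unshifted lists called. All genes were simulated as independent, whereas the estimated correlation was 0.32 for the interferon list. These runs therefore do not show how often the preset correlation calls a list falsely when its genes move together. The covariance expected from shared controls was simulated 20 times from each gene's own residual spread, also pooled over the 3 groups. Alternatives covered the intensity filter, the probe summary, renormalization, the variance model, array weights, thresholds, the arrays in the fit, the list test and leaving out each array.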

Results

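Primary cultures were grown from interscapular brown adipose tissue, a fat depot that burns fuel to make heat, of male C57BL/6 mice aged 5 weeks. A fraction enriched in precursor cells was plated, given insulin in rising doses and collected at about day 9. The compounds were given during differentiation according to the design text, while the sample labels name 9 days in vitro, so the length of exposure is not settled. Each of 3 groups held 3 cultures with subject numbers of their own: a vehicle control (DMSO, subjects 1 to 3), HA155 at 2.5 µM (subjects 4 to 6) and 1-oleoyl lysophosphatidic acid (LPA) at 5 µM (subjects 7 to 9). HA155 inhibits autotaxin, the secreted enzyme that makes the signalling lipid LPA. The comparisons ask which genes respond to the enzyme's inhibitor and which to its product, as the series design states. Whole-genome expression was measured on 9 Affymetrix mouse gene arrays, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.08. The labels describe 3 cultures per condition, so the p-values measure the spread between cultures.

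The LPA arrays lay apart from the rest. The first principal component held 66.7% of the variance, with the LPA arrays between 19.6 and 28.7 and the others between -15.5 and -7.28. LPA array 8 correlated least with the other groups (mean r = 0.970 across probes). Of 13335 genes tested, 3273 differed among the 3 groups by limma's moderated F at an adjusted p below 0.05.

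Thrsp, a regulator of lipid synthesis, fell by 2.23 on the log2 scale (SE 0.09, limma adjusted p = 1.44e-07), from 10.8 in control to 8.56 with LPA (n = 3 each). Acvr1c (log2 change -2.19), the carboxylesterase Ces1d, the adipokine Retn (-1.95), the insulin-responsive glucose transporter Slc2a4 (-1.94) and the lipid-droplet protein Cidec (-1.88) followed. Orm1 (-1.86), Adig (-1.85), Gpd1 (-1.85) and Cox8b (-1.85) completed the 10 largest falls. The largest rise was in Ccn1, a matrix-associated signalling protein, at 1.88 (SE 0.09, limma adjusted p = 2.33e-07). Next came the immediate-early transcription factors Egr1 (1.57) and Nr4a1 (1.50), the smooth-muscle microRNA gene Mir145a (1.52), Abi3bp (1.41), Il1rn (1.38), Mamdc2 (1.38), Ccn3 (1.36), Cxcl5 (1.35) and Wfdc17 (1.34). In all, 1621 genes rose and 1445 fell, and of those changed by at least 1 on the log2 scale 30 rose and 119 fell.

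All 35 tested genes of the general adipocyte list fell with LPA (35 adjusted over the list alone), with a median log2 change of -1.24, and all 35 fell when LPA array 8 was left out. Adiponectin (Adipoq) fell by 1.35 and the fatty-acid binding protein Fabp4 by 0.65. Leptin (Lep) fell to a mean of 5.59 in the LPA arrays, at the level of the intensity filter, so that the size of its fall is uncertain. The adipogenic transcription factors Pparg and Cebpa fell by 0.46 and 0.58. Of the brown adipocyte list, 10 of 23 tested genes fell and 1 rose (10 and 1 adjusted over the list alone), led by Cox8b and Cox7a1 (-1.84), muscle- and brown-fat-type subunits of cytochrome oxidase. The coactivator Ppargc1a fell by 0.60, and Prdm16 measured -0.23 (limma adjusted p = 0.125). Ucp1, the uncoupling protein of brown fat, Cidea and Dio2 lay below the intensity filter, and in a fit without it none of the 3 passed for LPA (limma adjusted p = 0.833, 0.460 and 0.881). Enpp2, the autotaxin gene, and Lpar5 were not analysed here.

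Genes of fuel use fell as groups with LPA. In mitochondrial respiration, 43 of 47 genes fell and none rose (45 fell adjusted over the list alone), with Cyc1 at -0.95 and Ndufb9 at -0.85. In fatty-acid oxidation, 20 of 24 fell (20 adjusted over the list alone), with Eci1 at -1.03 and Acadm at -1.02. In lipogenesis, 17 of 20 fell (17 adjusted over the list alone), with Acaca at -1.40 and Fasn at -1.25. In glycolysis and insulin signalling, 13 of 22 fell and 3 rose (14 and 4 adjusted over the list alone). Limma's camera test placed these lists and both adipocyte lists below the other genes (adjusted p = 2.01e-05 or less), and they held with an estimated correlation (adjusted p = 0.0264 or less). Of 18 cholesterol synthesis genes 9 fell and 1 rose (11 and 1 adjusted over the list alone), with an adjusted p of 5.52e-05 by camera and 0.13 with an estimated correlation.

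Several lists rose with LPA. In the preadipocyte and anti-adipogenic list 14 of 25 genes rose and 1 fell (17 and 1 adjusted over the list alone), among them Sfrp1 (0.91) and the precursor-cell receptor gene Pdgfrb (0.70). In the Wnt list 15 of 43 rose (16 rose and 1 fell adjusted over the list alone), with Dkk3 at 0.94 and Sfrp2 at 0.79; both of these and Sfrp1 encode secreted proteins known as Wnt antagonists or modulators. In the inflammatory and chemokine list 15 of 27 rose and 3 fell (15 and 4 adjusted over the list alone), with Ccl9 at 1.27 and Il33 at 0.73 but Cxcl9 at -0.95. These 3 lists passed camera (adjusted p = 0.000346 or less) and held with an estimated correlation (adjusted p = 0.0264 or less).

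Other lists that rose with LPA passed camera with the preset correlation only (adjusted p = 2.46e-05 or less). In the matrix list 28 of 39 genes rose and 3 fell (28 and 4 adjusted over the list alone), with Mmp3 at 1.20 (adjusted p = 0.10 with an estimated correlation). In the BMP and TGF-beta list 24 of 38 rose (26 adjusted over the list alone), with Id2 at 0.76 (adjusted p = 0.054 with an estimated correlation). In the contractile list of SRF targets 15 of 29 rose (20 rose and 1 fell adjusted over the list alone), with Tpm1 at 0.78 (adjusted p = 0.092 with an estimated correlation). In the YAP and TAZ target list 12 of 20 rose and 1 fell (12 and 1 adjusted over the list alone), with F3 at 0.93 (adjusted p = 0.073 with an estimated correlation). In the immediate-early list 10 of 21 rose and 1 fell (10 and 1 adjusted over the list alone), with Ier2 at 0.86 (adjusted p = 0.052 with an estimated correlation).

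Markers of other cell types did not all move alike. Skeletal muscle genes, which share 1 gene (Des) with the contractile list, moved with the falls in adipocyte genes: 16 of 21 rose (17 adjusted over the list alone), with Myh1 at 0.98 and Actc1 at 0.76 (camera adjusted p = 5.26e-08, but adjusted p = 0.079 with an estimated correlation). The 5 muscle genes that did not pass were Myod1 (-0.03), Pax7 (-0.03), Myog (0.02), Ckm (0.05) and Tnni2 (0.15). None of 15 macrophage markers passed (0 adjusted over the list alone, median log2 change 0.01), nor did any of 3 blood-cell and 5 mesothelial markers (0 adjusted over the list alone, medians 0.02 and -0.05). Of 13 endothelial markers 2 rose and 1 fell (2 and 1 adjusted over the list alone, median -0.08), and of 8 Schwann-cell markers 1 rose, Ncam1 by 0.74 (2 adjusted over the list alone). Sox18, the endothelial marker that fell, lost its call in 4 of 17 alternative fits. Camera did not pass the Schwann-cell list (adjusted p = 0.053) or the other lists of this group apart from muscle (adjusted p = 0.81 or more). Proliferation genes also missed it (adjusted p = 0.12). Of 33, 3 rose (1 adjusted over the list alone), Ccnd1 by 0.42, Mcm4 by 0.28 and E2f1 by 0.30, the last 2 of which lost their call in 4 and 12 of 17 alternative fits.

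The remaining lists did not pass camera for LPA either (adjusted p = 0.28 or more). The LPA receptor gene Lpar1 rose by 0.67 and Lpar6 fell by 0.41, while Lpar4 measured 0.02 and Lpar2 0.11. In the autotaxin and LPA list 5 of 14 genes rose and 3 fell (5 and 4 adjusted over the list alone). Of the interferon list 1 of 19 rose (1 adjusted over the list alone), Ifit2 by 0.35. Of the unfolded-protein list 3 of 20 rose and 1 fell (3 and 1 adjusted over the list alone). The 3 that rose, Pdia4, Pdia6 and Trib3, lost their call in 12, 4 and 2 of 17 alternative fits. Of the oxidative-stress list 5 of 22 rose and 4 fell (6 and 4 adjusted over the list alone), with Mt2 at 0.80 and the catalase gene Cat at -0.69. Among 12 housekeeping genes 1 rose and 3 fell (4 and 3 adjusted over the list alone), with Sdha at -0.68. Gusb, the housekeeping gene that rose, lost its call in 11 of 17 alternative fits. The median of that list (0.06) and its mean (-0.05) differed in sign.

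**Figure D1:**
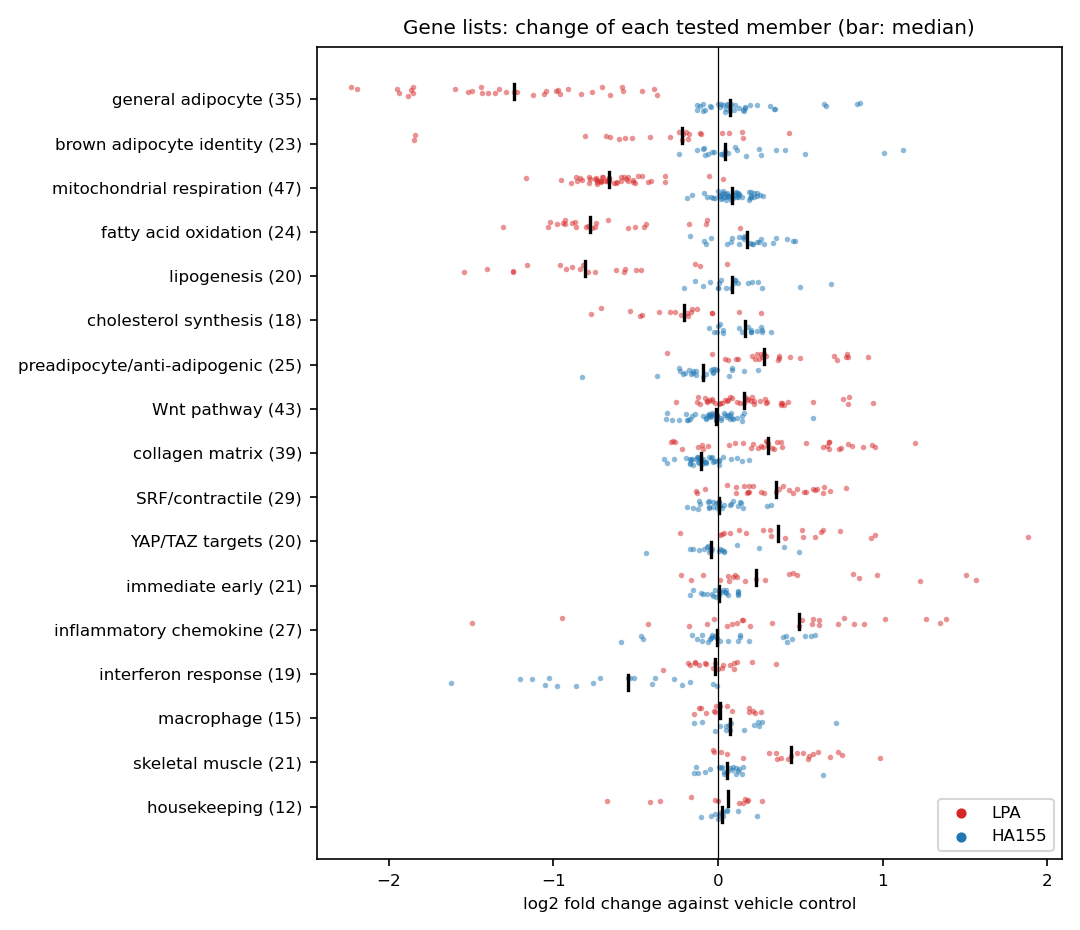
Log2 fold changes of each tested gene of 17 gene lists for LPA (red) and HA155 (blue) against the vehicle control, 1 point per gene, with a bar at the list median and the number of tested genes in brackets. The LPA points of the general adipocyte list all lie below 0, around a median of -1.24, and the HA155 points of the interferon list lie around a median of -0.54.

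HA155 changed far fewer genes than LPA did. Cox7a1 rose by 1.13 (SE 0.06, limma adjusted p = 8.96e-06), from 8.78 in control to 9.91 with HA155 (n = 3 each), and Cox8b by 1.01. The 3 control arrays held 1 identical value for Cox7a1, so its SE and p rest on an understated spread. Lrg1 (1.16), Lctl (1.13), the carboxylesterases Ces1f (1.09) and Ces1d (1.01), Orm1 (0.86), Pck1 (0.84) and the phosphatase Phospho1 (0.80) also stood among the 10 largest rises. So did the glycogen synthase Gys2, with a mean of 6.59 with HA155, but its control mean of 5.56 lay under the filter level of 5.59, so that its size and rank are uncertain. The largest falls were in interferon-stimulated genes: Ifit1 by 1.62 (SE 0.23, limma adjusted p = 0.00695), Rtp4 by 1.26, Oasl2 by 1.21, Bst2 by 1.13, Irf7 by 1.05, Ifit3 by 1.02, Gbp3 by 0.98, Trim30a by 0.87 and Usp18 by 0.86. Dlk1, a marker of preadipocytes, fell by 0.82 (SE 0.08, limma adjusted p = 0.000609).

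In all, 81 genes rose and 57 fell with HA155 at a limma adjusted p below 0.05, 138 in total, and 1082 had an unadjusted p below 0.05. The total depended on each control and HA155 array. It was 78, 39 and 75 without control 1, 2 and 3, 44, 47 and 56 without HA155 array 4, 5 and 6, and 232 without LPA array 8, which enters this comparison only through the shared estimate of the spread. All 138 genes kept their sign when any array was left out, but this was fixed in advance, since their groups did not overlap. Of the 39 genes named by rule that passed for HA155, 21 lost their call in at least 1 of 17 alternative fits, mostly those with 1 array left out. Ifit1 and Oasl2 lost it only without control 2 (limma adjusted p = 0.0565 and 0.0703). Pck1, Phospho1, Ifit3, Gbp3, Trim30a and Usp18 lost it in 2 to 7 fits. Cox7a1, Cox8b, Cidec, Lep, Bst2, Irf7, Rtp4 and Dlk1 kept theirs in all 17.

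Of 19 tested interferon genes 12 fell with HA155 (15 adjusted over the list alone), with a list median of -0.54 (limma camera adjusted p = 6.17e-28, but adjusted p = 0.080 with an estimated correlation). The number that fell was 3 without control 2, 4 without control 1, HA155 array 4 or HA155 array 5, 8 without HA155 array 6 and 12 without control 3. The list median stayed between -0.66 and -0.48. The 15 macrophage markers, measured beside them, had a median of 0.07 and none passed. Camera placed the macrophage list above the other genes (adjusted p = 0.0134, but adjusted p = 0.34 with an estimated correlation).

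The adipocyte, fatty-acid oxidation and lipogenesis lists lay higher with HA155 by camera with the preset correlation, and none of the 13 lists that passed it for HA155 held with an estimated correlation. In the general adipocyte list 6 of 35 genes rose (7 adjusted over the list alone), with Lep at 0.66 and Cidec at 0.65 (camera adjusted p = 2.37e-06, but adjusted p = 0.13 with an estimated correlation). Others of the 6 were less stable: Plin4 and Pck1 lost their call in 11 and 7 of 17 alternative fits, and Cd36 passed narrowly (limma adjusted p = 0.0485). Adipoq measured 0.16, Fabp4 0.16 and Pparg 0.00282, and none of these passed. In the brown adipocyte list 3 of 23 rose (6 adjusted over the list alone), namely Cox7a1, Cox8b and Pdk4 (camera adjusted p = 0.000496, but adjusted p = 0.080 with an estimated correlation). Pdk4 (0.53) lost its call in 8 of 17 alternative fits. In a fit without the intensity filter Cidea was higher with HA155 (limma adjusted p = 0.00108), at a mean of 6.39, while its control mean of 4.92 lay under the filter level of 5.59, so that no exact fold is given. Ucp1, under that level in both groups, did not pass (limma adjusted p = 0.96). In fatty-acid oxidation 4 of 24 rose (11 adjusted over the list alone), with Acaa2 at 0.42 and Hadhb at 0.45 (camera adjusted p = 8.77e-12, but adjusted p = 0.13 with an estimated correlation). Hadhb lost its call when any 1 of the control or HA155 arrays was left out. In lipogenesis 2 of 20 rose (5 adjusted over the list alone), with Acacb at 0.68 (camera adjusted p = 0.000451, but adjusted p = 0.11 with an estimated correlation).

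No gene of the mitochondrial respiration list, which does not hold Cox7a1 or Cox8b, passed with HA155 (0 of 47, and 0 adjusted over the list alone), although camera placed the list higher (median 0.08, adjusted p = 4.67e-05, but adjusted p = 0.21 with an estimated correlation). The same held for cholesterol synthesis (0 of 18, 3 rose adjusted over the list alone, median 0.16, adjusted p = 4.05e-05, but adjusted p = 0.19 with an estimated correlation) and proliferation (0 of 33, 0 adjusted over the list alone, median 0.08, adjusted p = 0.0134, but adjusted p = 0.63 with an estimated correlation). In the oxidative-stress list Gsta4 and Mt2 rose (2 of 22, 3 adjusted over the list alone, camera adjusted p = 7.79e-05, but adjusted p = 0.13 with an estimated correlation), with calls lost in 9 and 10 of 17 alternative fits. Camera placed 3 lists lower besides interferon. The matrix list had 1 of 39 genes that fell, Eln at -0.33 (3 adjusted over the list alone, adjusted p = 2.37e-06, but adjusted p = 0.23 with an estimated correlation). Eln lost its call without control 2 or 3 or HA155 array 4, 5 or 6 (adjusted p up to 0.131). The preadipocyte list had 1 of 25, Dlk1 (2 adjusted over the list alone, adjusted p = 0.000585, but adjusted p = 0.13 with an estimated correlation). The endothelial list had 0 of 13 (1 adjusted over the list alone, median -0.09, adjusted p = 0.00456, but adjusted p = 0.13 with an estimated correlation).

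The other 14 lists did not pass camera for HA155 (adjusted p = 0.078 or more). Single genes that passed in them were Igfbp3 (-0.44) of the YAP and TAZ list, Myh1 (0.64) of the muscle list and, of the inflammatory list, Hp (0.42), Saa3 (0.39), Cxcl13 (0.53), Ccl9 (0.59) and Cxcl9 (-0.59). Igfbp3, whose 3 control arrays also held 1 identical value, lost its call without control 1, 2 or 3 or HA155 array 4 or 5 (adjusted p up to 0.121), Saa3 without control 2 or 3 or HA155 array 4, 5 or 6, and Cxcl9 without control 2. Cxcl13 lost its call in 10 of 17 alternative fits, and Myh1 and Hp in 0. Adjusted over the list alone, 2 rose and 1 fell of the YAP and TAZ list, 1 rose of the muscle list, and 7 rose and 3 fell of the inflammatory list. No gene passed in the Wnt, autotaxin and LPA, contractile, immediate-early, BMP and TGF-beta, glycolysis, unfolded-protein, Schwann-cell, blood-cell, mesothelial or housekeeping lists. Adjusted over the list alone, 1 rose in each of the Wnt and housekeeping lists, 1 fell in each of the autotaxin and LPA and the BMP and TGF-beta lists, and 0 passed in the others. Lpar1 measured -0.10 and Lpar6 0.09. For the YAP and TAZ, inflammatory and Schwann-cell lists the median and the mean change differed in sign.

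**Figure D2:**
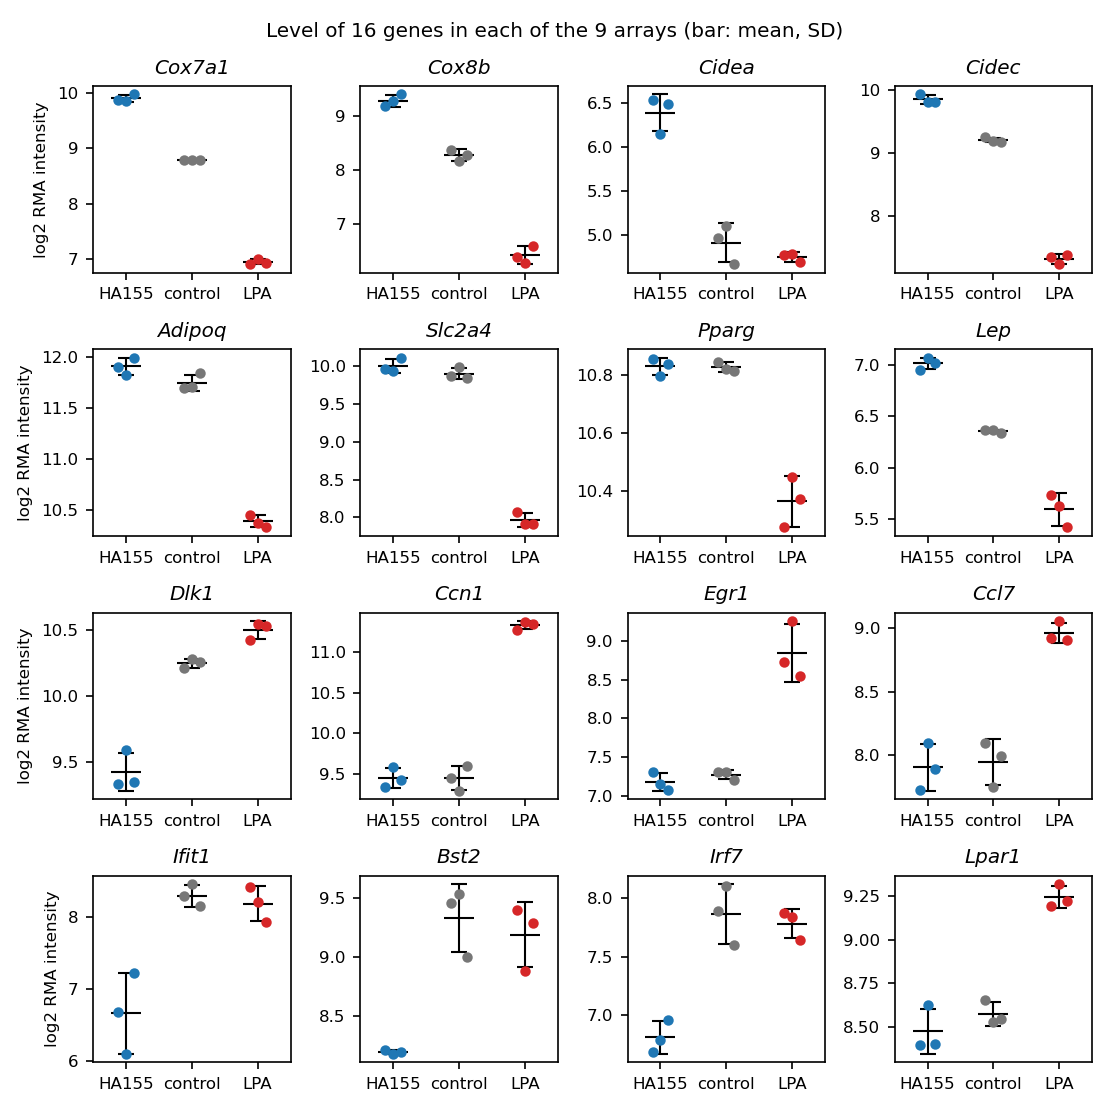
Log2 RMA intensity of 16 genes in each of the 9 arrays, 1 point per array, by group (HA155, control, LPA; n = 3 each), with the mean and SD as bars; the vertical axes differ between genes and do not start at 0. Cox7a1 is higher with HA155 (9.91) and lower with LPA (6.94) than in control (8.78), Ccn1 is higher with LPA (11.3), and Ifit1 is lower with HA155 (6.67).

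Set directly against each other, LPA and HA155 cultures differed in 3481 genes, 1826 higher and 1655 lower with LPA. The largest differences were lower with LPA: Ces1d by -3.01 (SE 0.09, limma adjusted p = 7.59e-09), Cox7a1 by -2.97, Cox8b by -2.86, Orm1 by -2.73, Ces1f by -2.61, Acvr1c by -2.53, Cidec by -2.53 and Thrsp by -2.36. Dnah3 and Lctl also ranked among the 10 largest, but their LPA means of 4.67 and 5.62 lay under and at about the level of the intensity filter, so that their size and rank are uncertain. The 3 control arrays held 1 identical value for Dnah3. Higher with LPA were Ccn1 (1.88), Egr1 (1.66), Egfl6 (1.59), the peptidase Anpep (1.55), Nr4a1 (1.54), Abi3bp (1.52), Ifit1 (1.51), the angiotensin-converting enzyme Ace (1.51), Mir145a (1.48) and Kcne4 (1.47). All 35 general adipocyte genes, 45 of 47 mitochondrial genes and 18 of 20 lipogenesis genes were lower with LPA (35, 46 and 18 adjusted over the list alone). Higher with LPA were 18 of 25 preadipocyte genes, 31 of 39 matrix genes and 14 of 19 interferon genes (20, 32 and 15 adjusted over the list alone). By camera 17 lists passed, and 9 held with an estimated correlation: both adipocyte lists, preadipocyte, Wnt, inflammatory, mitochondrial, fatty-acid oxidation, lipogenesis and glycolysis. Preadipocyte had an adjusted p of 0.0128 with an estimated correlation, matrix 0.064 and interferon 0.099. The median and the mean differed in sign for the proliferation, endothelial, mesothelial and housekeeping lists, none of which passed.

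The inhibitor and the product were compared through their changes against the same controls. Of the 138 genes that changed with HA155, 96 also changed with LPA, 79 in the opposite direction and 17 in the same one. Genes lower with LPA and higher with HA155 numbered 59, against 8.78 expected of independent lists, among them Cox7a1, Cox8b, Cidec, Lep and the fatty-acid transporter Cd36. Genes higher with LPA and lower with HA155 numbered 20, against 6.93, among them Dlk1 and Ace. Those higher with both numbered 12, against 9.85, and those lower with both 5, against 6.18. Unchanged groups simulated against shared controls gave 0 genes called in both, which the adjustment brings about where nothing changes and which sets no scale for the overlap, and part of the overlap in the same direction may come from the shared controls. As the HA155 count moves with single arrays, so do these: opposite and same-direction genes numbered 36 and 21 without control 1, 28 and 2 without control 2, 34 and 10 without control 3, 29 and 3 without HA155 array 4, 36 and 2 without HA155 array 5, 32 and 4 without HA155 array 6, 59 and 8 without LPA array 7, 132 and 29 without LPA array 8, and 80 and 9 without LPA array 9.

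Across all genes tested, which are not independent replicates, the fold changes with LPA and with HA155 had Pearson's r of -0.11 and Spearman's rho of 0.02, so the sign differed between the measures. Shared controls alone gave 0.497 and 0.466 in the simulation, which held no changed genes. Real changes with LPA widen the fold changes and shrink such a correlation. These 2 values are therefore no scale for the observed ones, and only the covariance is set against the simulation. The covariance was -0.00361, against 0.00431 simulated, a difference of -0.00792 with a jackknife SE over arrays of 0.00632. The 3 controls could not be split into parts of at least 2 arrays each.

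**Figure D3:**
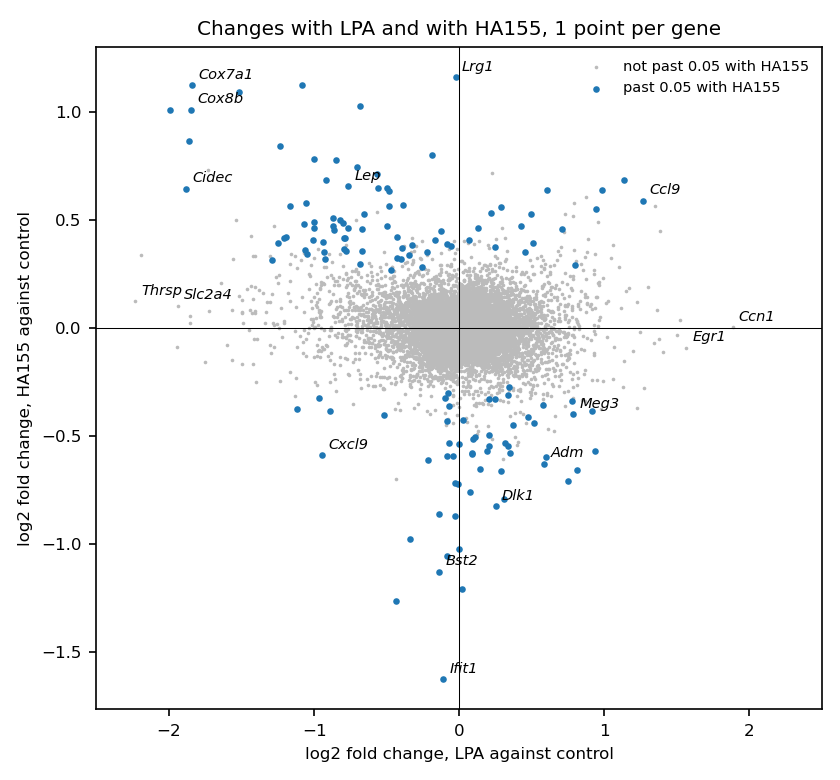
Log2 fold change with HA155 (vertical) against that with LPA (horizontal), both against the same 3 control arrays, 1 point per gene tested, with genes past an adjusted p of 0.05 for HA155 in blue. Cox7a1, Cox8b and Cidec lie at the upper left and Dlk1 and Adm at the lower right, while Ifit1 (-1.62 with HA155) lies near 0 with LPA (-0.11).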

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

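No alternative given here was chosen after the results were seen, and none reversed the direction of a called named gene or gene list. The count for HA155 against control (138) moved most: 86 without the intensity filter, 76 with every probe set tested, 338 with array weights, 1082 at an unadjusted p below 0.05, and 18 against a minimum log2 change of 0.26. That minimum left 883 genes for LPA against control and 1126 for LPA against HA155. The unadjusted and minimum-change counts differ by construction; the cause of the other moves was not tested. Leaving out each array in turn gave 39 to 232 genes for HA155 against control, 2293 to 3144 for LPA against control, 2588 to 3462 for LPA against HA155 and 2637 to 3157 for the 3 groups. The covariance above that simulated ran from -0.0115 to -0.0045 over these fits. With an estimated correlation 9, 0 and 9 lists passed for LPA against control, HA155 against control and LPA against HA155, and fry passed 7 for HA155. Lists past the threshold numbered 16 to 17, 11 to 15 and 17 to 18 when arrays were left out. The share of called genes that rose with HA155 was 58.7%, and 70.5%, 69.2% and 45.3% without control 1, 2 and 3. For LPA against control the share was 52.9%, and 45.6% without LPA array 9. For LPA against HA155 it was 52.5%, and 46.6% without LPA array 9. Which direction held more of the called genes thus changed with the arrays in the fit. Of 255 called values of named genes, 26 lost their call without control 2, 13 without the filter and 12 with only the groups compared in the fit. No paired analysis could be made from the labels, because the groups share no subject numbers. A preparation shared by cultures of different groups, if there was one, was therefore not modelled. Leaving out cross-hybridising probe sets by suffix was not run, as this array's identifiers carry none. The intensity filter limits what dim genes, Ucp1 and Cidea among them, can show.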

Other observations

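Except for the counts of other splits of the arrays, the tests in this part were chosen after the results were seen, and the criteria of those on cell-type markers, shared-control covariance and imprinted genes were revised after a first value was seen.

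A smaller group of 17 genes changed the same way with both compounds, and some of them are given here. The 12 higher and 5 lower with both lay near the 9.85 and 6.18 expected of independent lists. The chemokine Ccl9 rose by 1.27 with LPA and 0.59 with HA155, the B-cell chemokine Cxcl13 by 0.49 and 0.53, the acute-phase gene Saa3 by 0.51 and 0.39, the metallothionein Mt2 by 0.80 and 0.29, the glutathione transferase Gsta4 by 0.43 and 0.47 and the myosin heavy chain Myh1 by 0.98 and 0.64. Cxcl9, an interferon-gamma-induced chemokine, fell by 0.95 and 0.59. With HA155 Cxcl13 and Mt2 lost their call in 10 of 17 alternative fits, Gsta4 in 9, Saa3 in 5, Cxcl9 in 1 (without control 2) and Myh1 in 0. Ccl9 passed narrowly with HA155, and its value there was not followed over these fits. Shared controls push changes toward the same sign.

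Imprinted genes drew attention because Dlk1 and Meg3, which lie in the same imprinted cluster, were higher with LPA (0.25 and 0.79) and lower with HA155 (-0.82 and -0.40). A list of imprinted genes was then assembled with these 2 in it, so that at most the 18 others bear on the hypothesis that imprinted genes move together. The 18 still hold Rian, a gene of the same cluster, and so are not fully independent of the 2. Of these 18, 4 rose and 1 fell with LPA (median 0.17, limma camera p = 0.0244, but p = 0.17 with an estimated correlation), which leaves it open. With HA155 none passed alone, and the list lay lower (median -0.15, limma camera p = 3.28e-07, and p = 0.0125 with an estimated correlation). Between LPA and HA155 11 of 18 were higher with LPA (limma camera p = 0.0277 with an estimated correlation). These p-values are not adjusted over the 3 comparisons or for the choice of the list.

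Adipocyte genes fell with LPA, and this does not rest on LPA array 8, the array farthest from the others, since 35 of 35 general adipocyte genes fell without it. A lower share of adipocytes, which would raise markers of all other cell types alike, may account for it and stays open. Over 64 markers the changes differed between 6 lists (permutation p = 3.00e-05, and 0.00036 at a minimum level of 6). They also differed between the 5 lists left at a minimum level of 6.5 (permutation p = 0.0141). For the 18 markers of the 4 lists left at 7 or more no difference was detectable (permutation p = 0.20). Without the muscle list the permutation p was 0.099 or more at each level, and in muscle against macrophage markers alone, the form tried first, it was 8e-05 to 0.0188; all of these treat genes as independent, which they are not. A change in muscle-like cells stays open, as does a direct action of LPA on adipocyte genes, which the design names and these data cannot separate from cell number, and a batch of cultures that follows the groups. Of the 10 splits of the 6 arrays, too few for a share under 0.05, 1, the real one, gave as many genes (3066; highest other 0).

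Interferon genes fell with HA155. The vehicle cultures varied too: set against the control means, the list median was 0.05, 0.15 and -0.21 in control 1, 2 and 3. It was -0.61, -0.67 and -0.47 in HA155 array 4, 5 and 6. A loss of macrophages would lower their markers too, but the 15 tested had a median of 0.0735 with HA155. Several lay close to the intensity filter (Csf1r at a mean level of 5.70, Cd14 at 5.65), where a fall could hardly show. The 4 with a level of at least 6.5, picked later, had a median of 0.19 and a lowest value of 0.01. These 4 did not fall, but so few genes cannot exclude a loss of macrophages, which stays open. A single array could not carry the shift, as the list median stayed at -0.484 or lower whichever of the 6 arrays was left out, though the genes past the threshold then numbered 4, 3 and 12 without control 1, 2 and 3 and 4, 4 and 8 without HA155 array 4, 5 and 6, and the list test did not hold with an estimated correlation (adjusted p = 0.080). Less LPA signalling under the inhibitor stays open, since added LPA left the list at a median of -0.0156 but LPA made by the control cultures was not measured; an action of HA155 apart from autotaxin and a batch of cultures were not tested. Of the 10 splits, too few for a share under 0.05, 1 gave as many genes for HA155 against control (138; highest other 0).

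HA155 and LPA moved a set of genes in opposite directions, and that adipocyte genes follow the supply of LPA both ways is a hypothesis. The 119 genes that LPA lowered at least 2-fold had a median HA155 change of 0.12, above the 0.0261 that bounds random sets of like level, with 19 called higher and 1 lower, but random sets treat genes as independent, which adipocyte genes are not, and the general adipocyte list did not hold for HA155 with an estimated correlation (adjusted p = 0.13); the 30 that LPA raised as much did not mirror this, with a median of 0.06 and 17 above 0. Noise of the shared controls pushes the other way, but the covariance lay below the simulated one by -0.00792 with a jackknife SE of 0.00632, so chance between arrays is not excluded over all genes. A change in adipocyte share alone, taken as a straight line on the LPA changes, did not account for the pattern in full. Among the 119 genes the HA155 changes varied 9.95 times as much around that line as their errors allow (95% bootstrap interval 6.52 to 13.6). The ratio leaves out the error of the LPA changes and any curve, and the bootstrap treats genes as independent. A change in share of another form is therefore not excluded. Chance is not excluded for the share of the genes that differed between LPA and HA155 whose control mean lay between (2525 of 3481, 72.5%), which 28 of 100 drawn splits of the 9 arrays reached (highest other 94.1%).

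For LPA against HA155, 1 of the 10 splits gave as many genes (3481; highest other 0), again too few for a share under 0.05. For the 3 groups, only the real one of 100 drawn splits, of 280 possible, gave as many genes by the moderated F (3273). The highest other gave 2814 and was the 1 other drawn split that kept the LPA arrays together, while the 98 that mixed them gave 14 or fewer. The count thus sets the LPA arrays apart from the rest. It does not bear on control against HA155, and a batch that follows the groups could give it too.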
